A study of Mus musculus with 2 samples.

How the data were processed

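The labels describe CD45-positive cells sorted from digested lungs of mice, 7 weeks after a first urethane dose, from 1 wild-type and 1 Siah1a/2 knockout sample. The deposited matrix holds UMI counts per gene and cell barcode, not normalised, as whole numbers, made with Cell Ranger 6.1.2 per the file headers and the submitters' processing notes, which also name the genome build mm10. Whether reads were subsampled when the libraries were joined, and which gene annotation was used, is not given in the sources used here. Barcodes end in 1 or 2. No label ties an ending to a sample, so the libraries stayed without a genotype, and neither order nor the level of any gene was used to assign one.

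Cells with at least 500 genes and at most 10% mitochondrial UMIs were kept, which left out 456 barcodes of library 1 and 366 of library 2. Scrublet, as built into scanpy 1.11.5, was run in each library at its automatic threshold. It called 0 cells in library 1 and 1 in library 2, under the 0.5% set beforehand, so it was taken as not having worked and no cell was removed. Clusters with markers of more than 1 lineage stayed unnamed: those in which at least 50% of cells held 2 or more UMIs of Cd3 genes and 5 or more of macrophage genes, a level set after the data were seen. Cluster 17 met it and held 363 cells of library 1 and 283 of library 2.

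Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes within libraries gave 30 principal components, and each cell was joined to its 20 nearest neighbours. Edges were weighted by the overlap of neighbour sets and clustered with the Leiden method (igraph 0.11.9) at resolution 1. The filter, the variable genes, the components, the resolution, the markers and the gene lists were set before the data were examined. The kind of graph and the number of neighbours were not. At least 5 clusterings were looked at, this one included. Earlier ones used another edge weight and 15 neighbours, with a called cell or a haemoglobin-rich barcode left out or kept. They drew the border between the monocyte and macrophage classes differently, and between a pair of them that differed only in the processor's arithmetic it still moved. Their values are not given because they could not be recomputed exactly. The present graph rounds values at each step so that it does not depend on the processor. It was kept for that reason, but the choice was made after the classes given by the earlier ones had been seen. How far the classes still move is given by 5 other random seeds, 15 neighbours and the other alternatives.

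A cluster took the name of the class whose markers had the highest median log2 fold over the other cells. The fold had to be at least 2 times, with at least 3 markers at that fold. Clusters with a median depth under the library median divided by 3 and without an own marker among the top 10 genes stayed unnamed. At other settings this rule gave names that the text does not use, such as fibroblast at resolution 2, and no cDC1 or classical monocyte class at resolution 0.5. Classes with at least 50 cells in each library were compared.

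UMIs were summed per class and library. No test was run and no p-value is given, because each kind of sample had 1 library. Sums have exact Poisson intervals, shares exact Clopper-Pearson intervals, and ratios exact conditional binomial intervals, all at 95%. Cells are not replicates, so these intervals say nothing about animals. Log2 ratios used a pseudocount of 0.5 UMI and genes with at least 50 UMIs in both sums together. Named genes were Siah1a, Siah2 and Siah1b first, then, among genes at 50 or more CPM (UMIs scaled to the class total) in a library, the 10 highest and 10 lowest log2 ratios whose interval excludes 0. Other names are list members with the largest ratios or leading genes of clusters, and genes chosen after their values were seen are said to be so. For monocytes, T cell-like and regulatory T cell-like cells a selection of these genes is given. List medians were set against 10000 random lists of the same size matched on mean expression, as a description of these libraries. For shares of cells with a UMI, cells were also thinned to 3000 UMIs, leaving out 567 and 456 shallower cells.

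The ratio step was tested on simulated data for the macrophage-like class over 11036 genes, of which 67 were altered 1.5 times, 66 were altered 2 times and 64 were altered 4 times. The interval excluded 0 in the right direction for 80.6%, 97.0% and 100.0% of these, and for 4.74% of unaltered genes. Counts of both libraries were drawn by Poisson sampling from their pooled profile, the model that the intervals assume. These shares therefore leave out spread between cells and libraries, and the share for unaltered genes was largely fixed in advance. Coordinates come from GENCODE M21, used only for the 54349 of 55401 gene IDs that matched with their version. Genes that share reads with near-identical copies, such as Rpl10-ps3, Rpl9-ps6 and Ftl1-ps1, have uncertain counts.

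Other settings chosen in advance were no cell filter, a stricter filter (1000 genes, 5% mitochondrial), resolutions 0.5 and 2, each library on its own, thinning, a pseudocount of 5, at least 20 UMIs or no count filter, and TMM scaling with edgeR 4.0.16. Keeping called doublets is the same as the values reported. Added after seeing the data were leaving out cells with a Scrublet score over 0.25, leaving out the haemoglobin-rich barcode, 15 neighbours, other seeds, and monocytes and macrophages together. Matching of transcript ends used BLAST+ 2.17.0.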

Results

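By the labels, single immune cells from the lungs of urethane-treated mice were profiled by droplet-based RNA sequencing. Urethane is a carcinogen that induces lung tumours. The labels describe 1 wild-type and 1 Siah1a/2 knockout sample, sorted for CD45, the surface protein shared by white blood cells, and taken 7 weeks after the first dose. Siah1a and Siah2 encode RING-type ubiquitin ligases. The deposited matrix held the barcodes of 2 libraries, and the barcode suffix that separates them names no genotype. The libraries are therefore given as library 1 and library 2, without a genotype, and no comparison of genotypes was made. There was 1 library of each kind, so no difference below has a replicate check, and all intervals are exact 95% intervals that cover counting error only.

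Library 1 held 8522 barcodes and 86227008 UMIs, with a median of 8303 UMIs and 2611 genes per barcode. Library 2 held 6479 barcodes and 59459790 UMIs, with a median of 7546 UMIs and 2502 genes. The cell filter kept 8066 cells of library 1 and 6113 of library 2. The median mitochondrial share of UMIs in kept cells was 1.24% and 1.47%.

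The study asks about alveolar macrophages, the resident macrophages of the air spaces, and no cluster took their name. Some of their listed markers did lead other clusters, such as Ear2 and Fabp4 in the non-classical monocyte-like cluster. Over all barcodes of both libraries, Ear1, Fabp1, Car4 and Cidec had 0 UMIs each. Marco, a scavenger receptor of alveolar macrophages, had 5 UMIs in library 1 and 0 in library 2, and Siglecf had 55 and 69. A count of 0 allows up to 3 UMIs in the matrix by counting error, as a one-sided limit, while the intervals are two-sided. Genes that other cells also use were present, such as Chil3 with 11591 and 13042 UMIs and Mrc1 with 5125 and 3272. States of alveolar macrophages could therefore not be compared. The genes lie apart from each other in the genome (GENCODE annotation of GRCm38): Marco on the minus strand of chromosome 1 from 120474538 to 120505024, and Car4 on the plus strand of chromosome 11 from 84957786 to 84966044.

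The cells were mostly T cell-like, NK cell-like and macrophage-like. T cell-like clusters made up 23.5% of library 1 (interval 22.6 to 24.4) and 27.8% of library 2 (26.7 to 29.0). With each library clustered on its own they were 15.4% of library 1 and 27.4% of library 2. Cluster 9, unnamed and led by S1pr1, held 642 and 512 further cells, and 98.1% of its cells had T cell UMIs. NK cell-like clusters made up 16.0% (15.2 to 16.8) and 18.7% (17.8 to 19.7). Interstitial macrophage-like clusters, named from complement genes such as C1qa, made up 15.2% (14.5 to 16.1) of library 1 and 10.6% (9.86 to 11.4) of library 2. Classical monocyte-like cells made up 7.09% and 6.05%, and non-classical monocyte-like cells 5.44% and 4.69%. At resolution 2 the non-classical shares were 1.14% and 0.818%. The border between monocytes and macrophages moved with the clustering: with 5 other random seeds the macrophage-like share of library 1 went as low as 9.71%, and the classical monocyte-like share lay between 4.62% and 9.65%. The seed with 4.62% in library 1 gave 5.22% in library 2, so the order of the libraries turned for classical monocyte-like cells. Both kinds of monocyte and the macrophages together made up 27.8% (26.8 to 28.8) of library 1 and 21.4% (20.3 to 22.4) of library 2, a sum formed after the data were seen. With each library clustered on its own this sum was 21% and 23.2%, and the macrophage-like share was 7.43% (6.86 to 8.02) and 10.3% (9.55 to 11.1), so the order of the libraries turned for both.

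**Figure D1:**
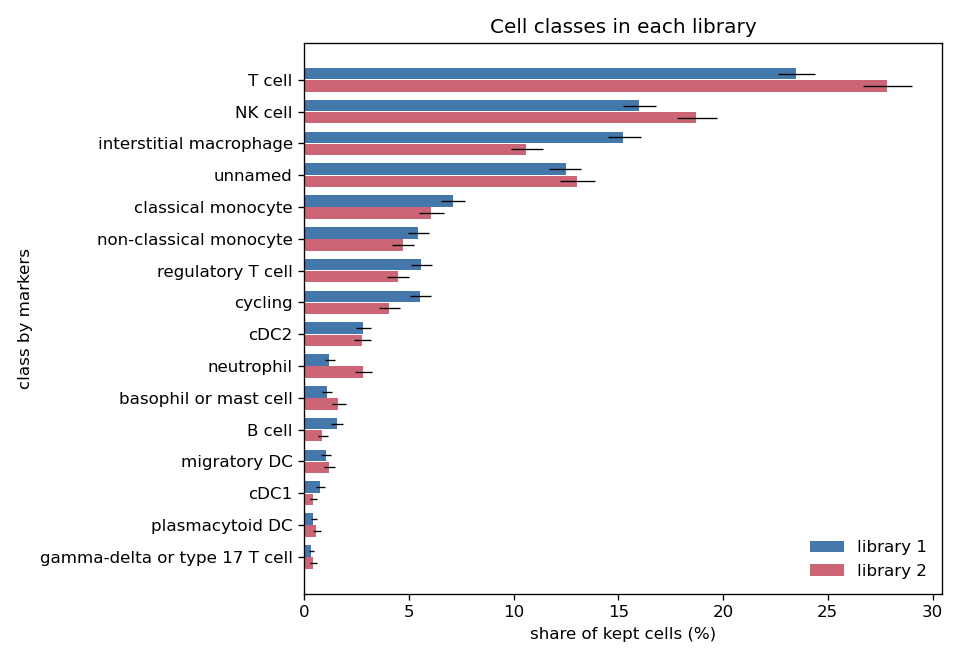
Share of kept cells in each marker-named class (percent, horizontal axis) for library 1 and library 2; black lines are exact 95% binomial intervals that cover counting error only. Interstitial macrophage-like cells stood at 15.2% in library 1 and 10.6% in library 2, an order that turned with each library clustered on its own, while NK cell-like cells stood at 16.0% and 18.7%.

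Regulatory T cell-like cells, which carried Foxp3 and Il10, were 5.59% (5.10 to 6.12) of library 1 and 4.47% (3.96 to 5.01) of library 2. Neutrophil-like cells, led by S100a9 and S100a8, were 1.20% (0.976 to 1.47) and 2.80% (2.40 to 3.24). With the stricter filter these shares were 0.637% and 1.52%. The median depth of these cells was 2644 UMIs. Basophil or mast cell-like cells were 1.07% and 1.62%, B cell-like cells 1.54% and 0.867%, and cDC1-like cells 0.756% and 0.409%. Unnamed clusters held 12.5% and 13% of cells. In 1 of them, cluster 17, 71.4% of cells held T cell and macrophage UMIs together, at a median of 16800 UMIs.

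The targeted genes were read in every class and library. Siah1a lies on the minus strand of chromosome 8 from 86724007 to 86745934, and Siah2 on the minus strand of chromosome 3 from 58674938 to 58692400. In the interstitial macrophage-like class Siah1a stood at 2.99 CPM, UMIs scaled to the class total (2.23 to 3.93) in library 1 and 11.9 (9.74 to 14.4) in library 2. Siah2 stood at 9.27 (7.88 to 10.8) and 27.5 (24.1 to 31.2). Classical monocyte-like cells gave 3.19 and 14.7 for Siah1a and 13 and 30.4 for Siah2. Non-classical monocyte-like cells gave 4.41 and 13.2 for Siah1a and 18.7 and 40.4 for Siah2. With cells thinned to 3000 UMIs the log2 ratio of library 2 over library 1 for Siah1a went from 2.18 to 3.80 (2.07 to 7.22) in classical monocyte-like cells, on 2 and 22 UMIs. In non-classical monocyte-like cells it went from 1.56 (0.69 to 2.54) to 1.55 (-0.06 to 3.52), an interval that includes 0.

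Among lymphoid classes, NK cell-like and regulatory T cell-like cells had log2 ratios of Siah1a and of Siah2 whose intervals include 0. In cluster 13 of the T cell-like class the log2 ratio of library 2 over library 1 was 0.63 (0.08 to 1.21) for Siah2. In cycling cells, mostly cluster 2, where 92.2% of cells held T cell UMIs, it was 0.46 (0.09 to 0.82). B cell-like cells held 10 and 1 UMIs of Siah1a, a log2 ratio of -1.03 (-6.98 to 1.27), an interval that includes 0. NK cell-like cells held Siah1a at 8.97 (7.49 to 10.7) and 10.1 (8.33 to 12.1), and Siah2 at 19.4 (17.2 to 21.8) and 22.9 (20.2 to 25.9). Regulatory T cell-like cells held Siah1a at 20.0 and 21.5 and Siah2 at 17.4 and 19.1. Thinned to 3000 UMIs, their log2 ratio of library 2 over library 1 was -0.58 (-1.83 to 0.47) for Siah1a and 0.81 (-0.28 to 1.91) for Siah2, so no difference was detectable at this depth. The log2 ratio of library 2 over library 1 for Siah1a was 1.99 (1.5 to 2.51) in macrophage-like and 0.17 (-0.21 to 0.55) in NK cell-like cells. For Siah2 it was 1.57 (1.27 to 1.87) and 0.24 (-0.01 to 0.49). A Siah1a UMI was found in 3.74% of macrophage-like cells of library 1 and 14% of library 2, at median depths of 11374 and 11355 UMIs. With cells thinned to 3000 UMIs these shares were 1.00% (0.519 to 1.75) and 3.29% (2.05 to 4.99), after leaving out 34 and 11 shallower cells. In NK cell-like cells the unthinned shares were 9.44% and 9.17%, at median depths of 10122 and 8928 UMIs. No class is known to lack these widely expressed genes, and which library holds the knockout is not known, so a background share could not be read. Siah1b, a close paralog, stood at 1.58 and 2.18 in macrophage-like cells. These levels were not used to give either library a genotype, and the part of each gene that was deleted is not given in the sources used here.

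**Figure D2:**
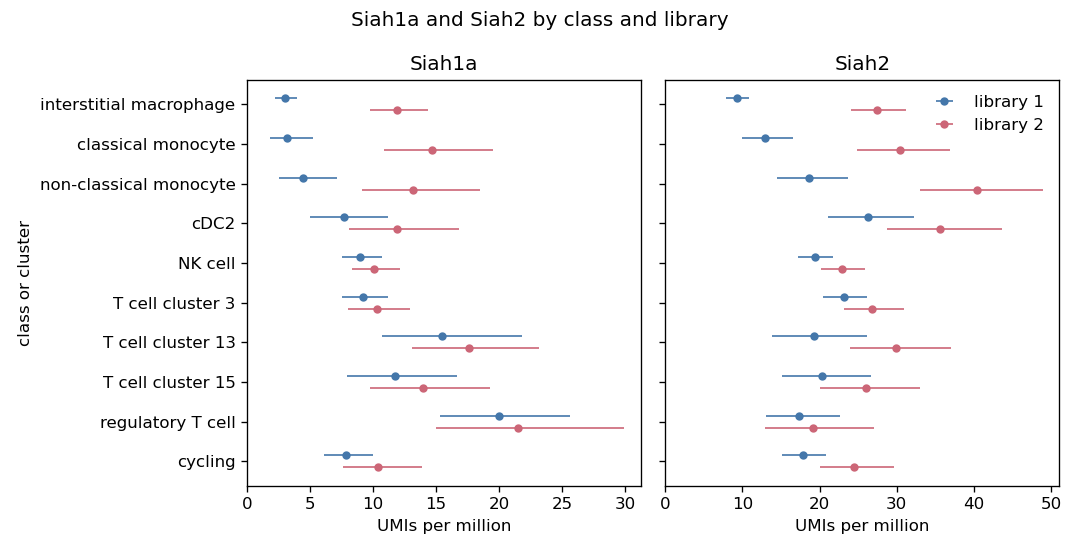
Siah1a (left) and Siah2 (right) in CPM of the class total (horizontal axis, linear) by class or T cell-like cluster; points are library 1 and library 2, and lines are exact 95% Poisson intervals for counting error only. In macrophage-like cells Siah1a stood at 2.99 and 11.9, and in NK cell-like cells at 8.97 and 10.1.

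In the interstitial macrophage-like class the largest ratio was that of Retnla, which encodes a secreted resistin-like protein. It stood at 165.4 CPM in library 1 and 0.573 in library 2, a log2 ratio of -8.04 (-9.80 to -6.95). Arg1, which encodes arginase, stood at 65.7 and 182.9, a log2 ratio of 1.48 (1.37 to 1.59). Cx3cr1, a chemokine receptor, had a log2 ratio of -1.04 (-1.13 to -0.95). The other genes lower in library 2 were Gm42031, Xcl1, Rpl35, H2ac8, Oas1a, Mir6236, Gpx4 and Gzmf, with log2 ratios from -3.18 to -1.10. The other genes higher in library 2 were Ifi208, G530011O06Rik, Rpl10-ps3, Ftl1-ps1, Rpl9-ps6, Ifitm1, Gm47283, Ifi206 and mt-Atp6, with log2 ratios from 1.09 to 4.50. Ratios beyond 2 times were seen for 24 of 3215 genes at the level required. Xcl1 and Gzmf are lymphocyte genes, and in cluster 11 of this class 41.8% of cells held T cell UMIs beside macrophage UMIs. Retnla was also among the leading genes of that cluster, which held 343 cells of library 1 and 143 of library 2.

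Gene lists in macrophage-like cells differed by small amounts. All 10 members of the MHC class II list, which present antigen to T cells, were detected: 8 lay above and 0 below a ratio of 1 beyond counting error. The list median was 0.32, at percentile 100 of 10000 random lists matched on expression, and H2-Aa stood at 4175 and 5804 CPM. Of 13 lipid uptake and storage genes 9 lay above and 0 below, with a median of 0.29, and Lpl had a log2 ratio of 0.51 (0.33 to 0.70). Of 23 profibrotic genes detected 13 lay above and 7 below, with a median of 0.12 at percentile 97.2. Arg1, Gpnmb and Mmp12 led that list, at log2 ratios of 1.48, 1.28 and 1.06. Gpnmb and Mmp12 went the other way in classical monocyte-like cells, at -1.71 and -2.33, and the border between these classes moved with the clustering. A shift of that border between the libraries can therefore not be told apart from a change within macrophage-like cells. Of 17 hypoxia and glycolysis genes 13 lay above and 3 below, with a median of 0.29. Only 9 of 20 mature alveolar macrophage genes were detected, of which 5 lay above and 1 below. Ribosomal protein genes lay below 1 for 67 of 83 members, with a median of -0.27. That list was not particular to macrophage-like cells. Its median lay below 0 in every class or cluster compared, from -0.30 in regulatory T cell-like to -0.01 in classical monocyte-like cells. Cholesterol synthesis genes lay above for 0 and below for 3 of 16, with a median of -0.12 at percentile 1.60. Dissociation and immediate early genes, a sign of handling, lay above for 12 and below for 2 of 18, with a median of 0.15 at percentile 99. Cell cycle genes lay above for 1 and below for 5 of 18, at percentile 1.4. Of 4 detected genes of the Y-linked and Xist list 2 lay above and 0 below, at percentile 99.7. The median of this list lay above 0 in every other class or cluster where it could be read, such as 0.28 in NK cell-like cells.

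**Figure D3:**
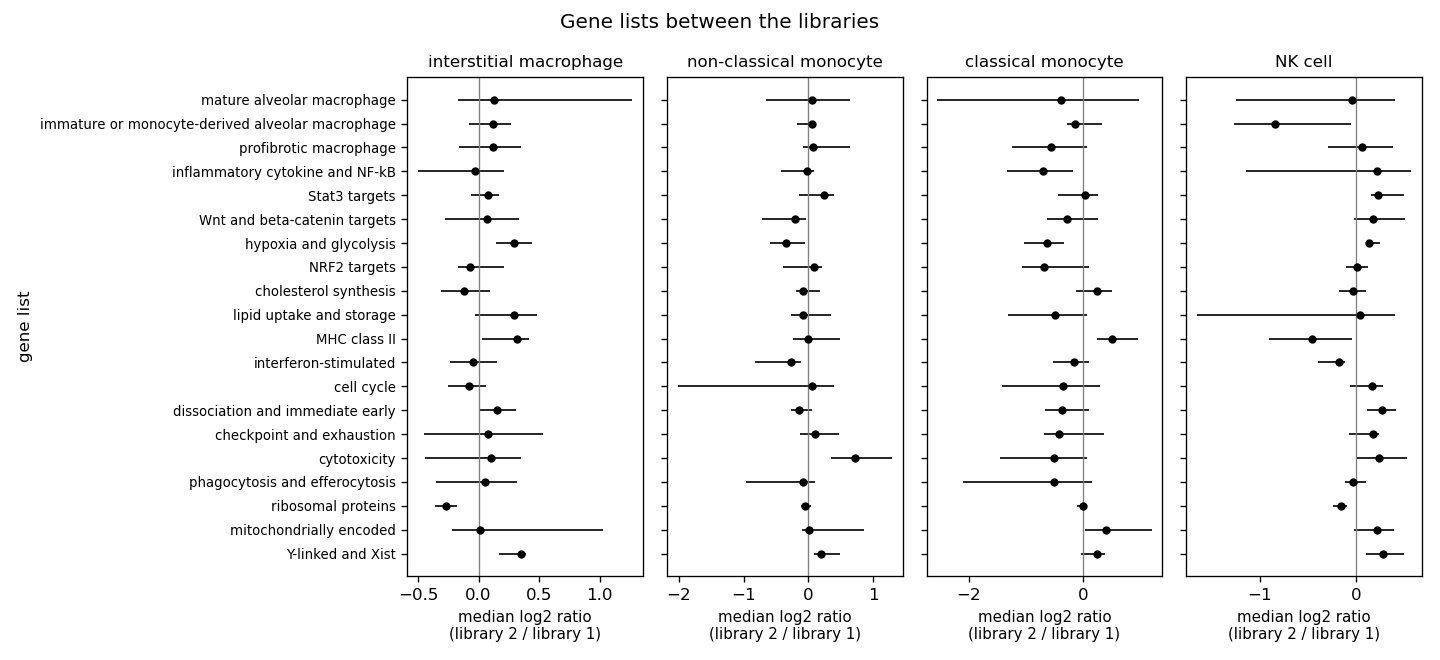
Median log2 ratio of library 2 over library 1 for each gene list (vertical axis) in 4 classes; lines are order-statistic 95% intervals of the median over list members, panels have their own horizontal scale, and the line at 0 marks equal levels. For lists with few members detected, such as the Y-linked and Xist list with 4, the line runs from the lowest to the highest member and covers less than 95%. The MHC class II list had a median of 0.32 in macrophage-like and -0.46 in NK cell-like cells, where Apoe, a macrophage transcript, was lower too at -1.66.

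In classical monocyte-like cells Hmox1, which encodes haem oxygenase, had a log2 ratio of -2.45 (-2.56 to -2.35), and Cxcl3, Mmp12, Nos2 and Gpnmb stood at -2.44, -2.33, -1.73 and -1.71. Hmox1, Nos2 and Gpnmb are themselves leading genes of this cluster. The profibrotic list had 2 members above and 14 below 1 of 21 detected, with a median of -0.57. The inflammatory cytokine list had 1 above and 13 below of 16, with a median of -0.70. Dissociation and immediate early genes, a sign of handling, had 4 above and 12 below of 18, with a median of -0.38, and the MHC class II list 7 above and 0 below of 8, with a median of 0.49. These values depend on where the clustering drew the border with macrophages. With 5 other seeds the number of genes beyond 2 times, 57 here, went as low as 21, the hypoxia and glycolysis median went from -0.63 to 0.15, the profibrotic median to 0.03 and the inflammatory cytokine median to -0.15. With 15 neighbours the MHC class II median was -0.01.

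In the monocytes and macrophages together, which that border does not divide, Hmox1 had a log2 ratio of -1.24 (-1.30 to -1.18) and Eno1, a glycolytic enzyme, -1.02 (-1.08 to -0.97). Eno1 was lower in lymphoid cells too, so its ratio was not particular to myeloid cells. It stood at -0.86 in NK cell-like cells and at -1.06, -1.18 and -1.30 in T cell-like clusters 3, 13 and 15. The inflammatory cytokine list had 4 members above and 12 below 1 of 18, with a median of -0.36. The hypoxia and glycolysis list had 3 above and 9 below of 18, with a median of -0.12, against 0.29 in macrophage-like cells alone. The profibrotic list had 5 above and 12 below of 23, with a median of -0.13, against 0.12 in macrophage-like cells alone. The lipid uptake and storage list had 4 above and 4 below of 14, with a median of 0.03, against 0.29 in macrophage-like and -0.49 in classical monocyte-like cells. The MHC class II list had a median of 0.28, with 8 above and 0 below of 10. Retnla had a log2 ratio of -7.56 (-8.87 to -6.67).

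In NK cell-like cells Ifng, the gene of interferon gamma, stood at 110.2 and 227.7 CPM, a log2 ratio of 1.05 (0.96 to 1.14). Cxcr4, a chemokine receptor, had a log2 ratio of 1.11 (0.94 to 1.28). Gzmg, a granzyme, had -1.04 (-1.12 to -0.95). The other genes lower in library 2 were Mir6236, Gm42031, Rpl35, Apoe, Ifi27l2a, Gpx4, Gm10076, Cd74 and Eno1, and the other genes higher were Ifi208, Rpl10-ps3, Gm47283, mt-Atp6, mt-Co2, mt-Co3, Rpl9-ps6 and Wdfy1. Ratios beyond 2 times were seen for 17 of 2938 genes.

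Of 10 cytotoxicity genes in NK cell-like cells 6 lay above and 1 below 1, with a median of 0.24, and Gzmb stood at 2660 and 3237 CPM. Of 18 interferon-stimulated genes 0 lay above and 13 below, with a median of -0.18, and Oas1a had a log2 ratio of -1.53 (-1.88 to -1.21). Oas1a was as low in macrophage-like cells, at -1.54 (-1.79 to -1.31), although the list median there was -0.05. Macrophage transcripts were lower in library 2 as well: C1qa had -1.59 (-1.84 to -1.35) and Apoe -1.66 (-1.84 to -1.48) in these NK cell-like cells. The MHC class II list was lower there too, at a median of -0.46. Other classes went the other way: Apoe had 1.92 (1.66 to 2.20) in neutrophil-like cells and C1qa 1.88 (1.45 to 2.35) in migratory DC-like cells. Macrophage-like cells had the larger share in library 1 with the libraries clustered together, and the smaller share with each on its own. Immediate early genes lay above 1 for 12 and below for 0 of 17, with a median of 0.27.

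T cell-like clusters were compared by number, since a cluster of that class had more leading genes of another class than its own. Cluster 3, led by Pdcd1, Cd8a and Lag3 among others, held 1178 and 867 cells. Of its 10 cytotoxicity genes 9 lay above and 0 below 1, with a median of 0.32, and Gzmb had a log2 ratio of 0.55 (0.52 to 0.59). The cytotoxicity median was 0.02 in cluster 13 and 0.10 in cluster 15. Macrophage transcripts were lower in library 2 in cluster 3 too, with C1qa at -1.50 (-1.79 to -1.23), and 11 of 17 dissociation and immediate early genes lay above and 2 below. Of 12 checkpoint genes 5 lay above and 2 below: Ctla4 had 0.87 (0.79 to 0.94) and Tox -0.33 (-0.43 to -0.23). Regulatory T cell-like cells had 7 checkpoint genes above and 1 below of 12, with a median of 0.28. Macrophage transcripts were lower in library 2 in these regulatory T cell-like cells too, with Tyrobp at -1.61 (-1.86 to -1.38) and the MHC class II list at a median of -0.61. Interferon-stimulated genes lay above 1 for 9 and below for 1 of 18 in regulatory T cell-like cells, with a median of 0.18, and above for 10 and below for 2 of 17 in cluster 15, with a median of 0.16. In cluster 13 they lay above for 0 and below for 9 of 15, with a median of -0.50. Dissociation and immediate early genes lay above for 6 and below for 5 of 17 in that cluster, with a median of -0.13. C1qa had a log2 ratio of -1.94 (-2.46 to -1.46) in cluster 13 and -1.91 (-2.48 to -1.40) in cluster 15, where 8 dissociation and immediate early genes lay above and 1 below of 17. Non-classical monocyte-like cells had 2 interferon-stimulated genes above and 12 below of 17, with a median of -0.27, and 1 dissociation and immediate early gene above and 11 below of 17, with a median of -0.14. In them 7 of 8 cytotoxicity genes lay above 1, and Gzmf, a granzyme of NK cells here, stood at 18.7 and 214.8.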

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

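Of the tests below, those of the cell filter, of lung epithelial transcripts, of a factor common to a library and of a chromosomal segment were chosen after the result they bear on was seen.

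Barcodes that the filter left out, which are not among the cells used for the reported values, held haemoglobin UMIs. In library 1 they held 361 (324.7 to 400.2), which was 0.0893% of their UMIs. In library 2 they held 13883 (13653 to 14116), or 3.27%. Both are above the 3 UMIs that a count of 0 allows. Kept cells held 1558 haemoglobin UMIs in library 1, of which 1500 lay in 1 barcode, and 86 in library 2. No explanation was tested.

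Several transcripts of alveolar macrophages, such as Ear1 and Fabp1, were near absent from both libraries. The cell filter did not remove them: Ear1, Fabp1, Car4, Cidec, Marco and Krt79 together had 0 UMIs among the 828851 UMIs of the barcodes left out. Reads discarded because another gene overlaps on the same strand are argued against within GENCODE M21. In it, 0% of the 6 markers under 30 UMIs had 50% of their exon bases overlapped. The annotation behind the matrix is not given, so overlaps with genes outside GENCODE M21 could not be seen. Cells of another origin than the sorted lung suspension, or files of another experiment, remain a candidate explanation. It predicts that lung epithelial RNA is missing too, and 5 lung epithelial genes reached at most 0.252 CPM. Without a library known to come from lung there is no level to set this against. The test could therefore only have counted against this explanation, and it decides nothing. Loss of these cells before or during sorting stays open, and no biological explanation was tested.

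Siah1a and Siah2 were lower in library 1 than in library 2 in macrophage-like cells, at a ratio of 3.22 (2.70 to 3.84) for both genes together. A difference in depth per cell is argued against by thinned cells, where the ratio was 2.58 (1.79 to 3.75). A factor common to all cells of a library is argued against as the whole cause by NK cell-like cells, at 1.16 (1.01 to 1.34). That interval also lies above 1, so a smaller contribution of such a factor stays open. Siah1a reads counted as Siah1b are argued against by a ratio of 3.08 (2.30 to 4.15) for Siah1a and Siah1b together. Genotype is the biological difference the design names; it was not tested, since neither library has one.

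Some 7 genes, each readable in at least 10 of 14 classes or clusters, lay beyond 2 times in the same direction in every one of these: Rpl10-ps3, Rpl9-ps6, mt-Atp6 and mt-Co3 higher in library 2, and Rpl35, Gm42031 and Mir6236 lower. Reads shared with near-identical copies may contribute: 85.7% of these genes had a transcript end matching another gene, against a median of 28.6% and a highest value of 85.7% in 1000 random sets. A chromosomal segment from another strain may also contribute, though not for mt-Atp6 and mt-Co3, which lie on the mitochondrial genome. Of the 5 nuclear genes 20% lay within 2 megabases of another or of Siah1a or Siah2, against a median of 0% and a highest value of 60% in random sets: Gm42031 lies 1.59 megabases from Siah1a on chromosome 8. Neither test decides with so few genes, and no biological explanation was tested.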

How the results depend on the processing

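The alternatives with other seeds, 15 neighbours, high doublet scores removed, the haemoglobin-rich barcode left out, and monocytes and macrophages together were chosen after the data were seen, as were the graph itself and the level for clusters of mixed lineage. No paired analysis was possible because each genotype had 1 library and no test was run, although both labels carry replicate number 1. Earlier clusterings on another graph, at least 4 of them, are not among the alternatives. Shares, as library 1 then library 2, are given for the largest classes, and for some of the others that moved; the cause was not tested. At resolution 0.5 interstitial macrophage-like cells were 21.2% and 16.0%, and monocytes and macrophages together 26.5% of library 1, unnamed clusters 5.73% and 5.35%, and gamma-delta or type 17 T cell-like 8.22% and 8.67%, against 0.310% and 0.409% as reported. At resolution 2.0 T cell-like cells were 27.9% and 32.2%, classical monocyte-like 11.8% and 9.83%, macrophage-like 9.06% and 6.72%, non-classical monocyte-like 1.14% and 0.818%, and together 22.0% and 17.4%. With no cell filter NK cell-like cells were 14.7% and 16.9%, macrophage-like 16.5% and 13.2%, and together 29.6% and 24.0%; T cell-like were 22.0% and classical monocyte-like 8.12% of library 1. With the stricter filter T cell-like were 26.1% and 31.4%, and classical monocyte-like 7.76% of library 1. With high doublet scores removed these were 24.7% and 7.74% of library 1. With the haemoglobin-rich barcode left out classical monocyte-like were 9.92% and 8.95%, macrophage-like 9.80% and 7.08%, and together 25.1% of library 1. The gamma-delta or type 17 class was 8.49% and 8.69% there. With each library on its own classical monocyte-like were 8.16% and 7.66%, together 21% and 23.2%, and macrophage-like 7.43% and 10.3%, so that the order of the libraries turned for the last 2. T cell-like were 15.4% and 27.4%, unnamed clusters 17.5% and 8.57%, and the gamma-delta or type 17 class 10.6% of library 1. Over 5 other seeds the lowest values were 13.6% and 15.5% for NK cell-like, 4.62% and 5.22% for classical monocyte-like, 9.71% and 7.02% for macrophage-like, and 24.6% together in library 1. At the seed with 4.62% and 5.22% the order of the libraries turned. The highest were 27.4% and 31.9% for T cell-like and 9.65% and 8.80% for classical monocyte-like. In classical monocyte-like cells genes beyond 2 times went to 21 and lists outside the middle 95% of random lists to 8 at the lowest seed, the hypoxia and glycolysis median to 0.15 at the highest, and the MHC class II median to -0.01 with 15 neighbours. With thinned cells the log2 ratio of Siah1a was 3.80 in classical monocyte-like cells and that of Siah2 1.22 in macrophage-like cells, and in cDC2-like cells Siah2 turned to -0.03 while Siah1a went from 0.62 to 2.96 (0.56 to 8.93), on 1 and 8 UMIs. In regulatory T cell-like cells thinning gave -0.58 for Siah1a and 0.81 for Siah2, both with intervals that include 0. With no cell filter Siah2 was 1.27 in macrophage-like cells and the mitochondrially encoded median of neutrophil-like cells turned to -0.07. With no filter on low counts the cell cycle median of neutrophil-like cells turned to -0.85. Of 1630 other values of list medians 1590 stayed within their spread, 36 moved and 4 turned. Not run were the 5 alternatives for alveolar macrophage states, as no such cluster was found. Siah ratios, counts of genes and list medians were not computed at resolutions 0.5 and 2.0 or with the stricter filter. Nor were they computed with each library on its own or with the haemoglobin-rich barcode left out. Those settings were read for shares only, so how far the ratios move under them is not known. Keeping called doublets changes nothing, as none was removed. Resolution 0.5 gave no classical monocyte-like or cDC1-like class, and on their own library 2 gave no cDC1-like and library 1 no plasmacytoid class. Depth limits the thinned Siah values and classes under 50 cells.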

Other observations

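The genes in the first 3 paragraphs were chosen after their values were seen. NK cell-like cells held high levels of granzymes beyond Gzmb. Gzmc stood at 6611 and 7074 CPM in libraries 1 and 2, Gzmf at 1539 and 1457, and Gzmd at 979.4 and 965.5. In T cell-like cluster 3 Pdcd1, an inhibitory receptor, stood at 429.1 and 438.4 beside Cd8a at 909.1 and 994.3.

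Basophil or mast cell-like cells held the mast cell proteases Cma1 at 56867 and 49670 CPM and Mcpt4 at 36056 and 28767. Mcpt8, a basophil protease, stood at 26.5 and 226.4. Cluster 23, led by Mcpt8, held 17 cells, all from library 2.

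Lyz2, a lysozyme gene of myeloid cells, stood at 19.0 (17 to 21.2) and 18.7 (15.9 to 21.8) CPM in macrophage-like cells. Its near-identical neighbour Lyz1 stood at 284.4 and 464.5. Reads can be split between these copies, so both levels are uncertain.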
